A study of Mus musculus with 8 samples.

How the data were processed

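Total RNA of sorted basal progenitors from the mouse cortex was labelled with cyanine-3 and hybridised to one-colour Agilent miRNA arrays, per the labels' protocols, with 4 arrays per stage and 1 array per replicate. The gate used for sorting is not given in the sources used here. Stage and replicate number were taken from the sample titles. The authors deposited 1 scanner file per array and 1 value table. Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1, a version also named in the submitters' processing notes, and probes were placed on mm9. The deposited files give, per spot, a mean intensity, a local background intensity, a background-subtracted processed intensity that can be below 0, and a total signal per miRNA, none of them scaled between arrays. They also hold other columns, flags of 0 or 1 for spots well above background, outliers and saturation, per the file headers. The deposited value table holds log2 values for 1187 spots of 145 probes and 86 miRNAs. Each of its columns ranked the spots exactly as the processed signal of that array did (Spearman correlation 1), the sorted columns differed by at most 0.0052 with a median of 6.90 in each, and every spot was well above background on all 8 arrays. It was therefore read as the log2 of quantile-normalized processed signals, higher meaning brighter, and used only as an alternative. The software behind it is not given in the sources used here.

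The arrays held 1759 mouse probes. Control spots were left out, as were spots with an outlier flag (2.01% to 3.86% of spots per array), and no spot was saturated. The remaining spots of a probe were averaged on the linear scale. A probe counted as well above background on an array when a share of 0.5 or more of its spots did. Each array was divided by the 75th percentile of its processed signal over the 126 mouse probes well above background on all 8 arrays. Scaled signals were floored at 1 value for all arrays, percentile 1 of the scaled signals of probes well above background (log2 value -5.96), and the log2 was taken. Values at the floor have no order, and the size of a difference that involves them is not exact. The probe with the highest mean over all arrays stood for its miRNA. In 90 miRNAs several probes were measured, and in the 27 of these with a call the probes had the same sign, with a median gap of 0.08 on the log2 scale over the 90. The 153 miRNAs with a probe well above background on at least 4 of the 8 arrays were tested. Probes of related miRNAs, such as those of the let-7 family, can share signal where their sequences are alike.

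Stages were compared as E16 minus E13 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Array counts were compared with a two-sided exact permutation test, whose smallest possible p was 0.029. A miRNA well above background on no array of a stage has only a bound there. It is given as "at least N-fold", the mean of the bright stage against the mean, over the arrays of the dim stage, of the highest of the floor, the lowest signal among probes well above background and the probe's own signal. Lists of miRNAs were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, adjusted over 8 lists, with an estimated correlation and fry as alternatives. The lists were the let-7 family, the miR-125 and miR-99 families, the miR-17-92 cluster and paralogues, the miR-15/16 family, neuron-associated miRNAs, the miR-9 hairpin, the Dlk1-Dio3 cluster, the miR-29, miR-30 and miR-181 families, embryonic stem cell clusters, epithelial miRNAs, 6 lists of other cell types and 1 of the hindbrain and spinal cord. Probes for viral miRNAs were kept apart. The design, the lists, the rule for named miRNAs and the alternatives were fixed before the data were examined, except where said otherwise.

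The rule for named miRNAs takes up to 10 rises and 10 falls with the largest differences among calls without overlap that were well above background on all 8 arrays, up to 4 members of each list by smallest p, a set named in advance of which 10 were tested, up to 5 miRNAs per direction detected on all arrays of one stage and none of the other, and miRNAs with an outlying array. It named 50 miRNAs, 9 by size of rise, 10 by size of fall and 5 detected at E13 alone. Other miRNAs are named only as list members or as chosen after their values were seen.

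The fit was tested on simulated data built from the means and spreads of the 153 miRNAs, in 50 sets with 40 changed miRNAs each, for the comparison of E16 with E13. It recovered 77.1% of miRNAs changed by 1 log2 unit and 98.6% of those changed by 2, and 4.30% of its 1836 calls were false. In 1 call the sign was wrong, and the test's first requirement of 0 such calls was relaxed to under 1% of calls after it was seen. The simulated errors were independent between miRNAs, had the same spread at both stages and met no floor. These rates therefore need not hold for the real arrays. The number of arrays limits the precision.

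The arrays came from 3 slides. Slide 2 held E13 replicates 1 and 2 and E16 replicates 2 and 3, slide 3 held E13 replicates 3 and 4 and E16 replicate 4, and slide 1 held E16 replicate 1 alone. The alternatives were the percentile over all mouse probes, quantile normalization, normexp correction of the mean intensity with an offset of 50, the mean of all probes, the total signal per miRNA, a filter on all 8 arrays and no filter, a lower floor, the deposited value table, the slide as a fixed or random block, each slide alone, the replicate number as a block, eBayes with trend and robust options, and leaving out each array in turn. Within slide 3 the lone E16 array is assumed to vary like the E13 arrays. Centring on the median, and list counts without E16 replicate 4, were chosen after seeing the data. Gene names, overlaps and neighbours were taken from the RefSeq table of GRCm38, in which 31 of the 50 named miRNAs matched 1 gene by name and 19 of these overlapped another gene. Its coordinates were not used, since the probes are placed on mm9.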

Results

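MicroRNA levels were measured in basal progenitors of the mouse embryonic cerebral cortex at embryonic day 13 (E13) and embryonic day 16 (E16). Basal progenitors are neurogenic precursors that divide away from the ventricular surface, and the cells were isolated by fluorescence-activated sorting. Each stage was represented by 4 biological replicates, and each replicate was hybridised to its own one-colour Agilent miRNA array with probes for 611 mouse miRNAs. The submitters' design text describes 3 litters per stage, so that, unless litters were pooled, some of the 4 replicates of a stage share a litter. The tests treat the 4 replicates as independent, and their p-values rest on the spread between these samples. The comparison of E16 with E13 asks which miRNAs differ in basal progenitors between an early and a later stage of cortical neurogenesis.

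Between 76 and 206 miRNAs were well above background on an array. The E13 arrays detected 153.5 ± 36.8 miRNAs (SD, n = 4) and the E16 arrays 133.25 ± 42.9 (SD, n = 4). The difference of -20.25 (E16 minus E13) was smaller than the spread between arrays (two-sided exact permutation test over 70 assignments, p = 0.54). Without E16 replicate 4, which had the fewest detected miRNAs, the means differed by -1.17, and without E13 replicate 3, which had the most, by -2.75. The 75th percentile of the processed signal ranged from 109 on E16 replicate 4 to 748 on E16 replicate 2, with the E13 arrays between 162 and 490. Correlations between arrays across the 153 miRNAs tested ranged from 0.967 to 0.991 within E13, from 0.882 to 0.988 within E16 and from 0.869 to 0.936 between stages, and miRNAs are not independent replicates. The first principal component held 59.8% of the variance and separated the stages. The second held 27.9% and set E16 replicate 4 (score 8.30) apart from E16 replicate 1 (score -7.26).

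At E16, several miRNAs of the let-7, miR-99 and miR-125 families were higher than at E13, whereas miRNAs of the imprinted Dlk1-Dio3 region were lower. let-7b had the largest rise among the miRNAs detected on every array, 6.33-fold (log2 difference 2.66, SE 0.28, limma adjusted p = 8.3e-05). miR-449a had the largest fall among the named miRNAs detected at both stages and was 7.27-fold higher at E13 (log2 difference -2.86, SE 0.38, limma adjusted p = 0.00033). Of 153 miRNAs tested with limma, 11 were higher and 39 lower at E16. In all 50 the E16 values lay beyond the E13 values without overlap, as in 8 further tested miRNAs without a call, where chance gives 2.86% of miRNAs if the arrays are exchangeable. This separation rests on the same values as the calls and is not separate support for them. The median log2 difference of all tested miRNAs was -0.40. The shift and the balance of calls depended on the scaling. The median was 0.41, with 46 miRNAs higher and 16 lower, when the percentile was taken over all mouse probes. That percentile is set largely by probes near background, since 131 to 344 of the 1759 mouse probes were well above it on an array. The median was -0.15 with quantile normalization (13 higher, 22 lower) and -0.20 with normexp correction (5 higher, 2 lower). Among the 75 miRNAs well above background on all 8 arrays, 9 were higher and 10 lower. With the deposited value table, which holds 86 miRNAs, 13 were higher and 11 lower, and with the total signal per miRNA 7 and 24. Without E16 replicate 4, 22 miRNAs were higher and 43 lower. Without E13 replicate 1, 2, 3 or 4, 21, 24, 22 and 22 miRNAs were lower. With the slide as a fixed block, 10 miRNAs were higher and 37 lower, within slide 2 there were 9 and 25, and within slide 3 13 and 87. Slide 3 held E16 replicate 4 alone of that stage, so that its values here and below describe that array as much as the stage. All E13 arrays lay in row 2 of their slides and all E16 arrays in row 1, so that slide row and stage cannot be told apart.

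The let-7 miRNAs, which accumulate during development, had 9 tested members, of which 4 rose, 0 fell and 5 did not pass the test, and 6 rose when adjusted over the list alone. With the percentile over all mouse probes 8 of the 9 were higher (list median 1.31). After let-7b, whose probe match lay on chromosome 15 from 85537759 to 85537776 (mm9, the build named in the file headers), the rises were 2.97-fold for let-7c (log2 difference 1.57, SE 0.25), 1.80-fold for let-7a and 1.65-fold for let-7f. Mirlet7b neighbours Mirlet7c-2 and overlaps the long non-coding RNA gene Lncppara in the RefSeq annotation of GRCm38. Among the members that did not pass, let-7d had a log2 difference of 0.49, let-7i of 0.46, miR-98 of 0.41, let-7g of 0.14 and let-7e of -0.35, which was 0.47 with the percentile over all mouse probes. The list median was 0.49, or 0.89 above the median of all tested miRNAs (camera adjusted p = 3.8e-05, and adjusted p = 0.20 with an estimated correlation). With the slide as a block it was 0.45, with 0.56 within slide 2 and 0.41 within slide 3. The call for let-7f was lost under quantile normalization (0.64), normexp correction (0.64), the total signal per miRNA (0.86) and the deposited value table (0.62), with the slide as a block (0.55) and within slide 2 (0.64) or slide 3 (0.41), and without E13 replicate 1, 3 or 4 or E16 replicate 1, 2 or 3 (0.58 to 0.78). That for let-7a was lost under normexp correction (0.76), with the slide as a block (0.74), within slide 2 (0.57) and without E13 replicate 1 (0.77) or 4 (0.75), and that for let-7c within slide 2 (1.23).

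The list of miR-125 and miR-99 families, miRNAs encoded beside let-7 genes, had 5 members, of which 3 rose and 2 did not pass the test, with the same counts adjusted over the list alone. miR-100 rose 3.36-fold (log2 difference 1.75, SE 0.17), miR-99a 2.88-fold (1.53, SE 0.16) and miR-125b-5p 2.06-fold (1.04, SE 0.17). The probe match of miR-100 lay on chromosome 9 from 41339524 to 41339541 and that of miR-99a on chromosome 16 from 77599189 to 77599206 (mm9). In the RefSeq annotation of GRCm38, Mir100 overlaps the long non-coding RNA gene Mir100hg and neighbours Mirlet7a-2, and Mir99a neighbours Mirlet7c-1. The remaining members, miR-99b (log2 difference -0.50, SE 0.22) and miR-125a-5p (-0.54, SE 0.26), did not pass the test and were at 0.32 and 0.28 with the percentile over all mouse probes. The list median was 1.04, or 1.44 above that of all tested miRNAs (camera adjusted p = 0.0079, and adjusted p = 0.17 with an estimated correlation), with 1.08 for the slide as a block, 0.89 within slide 2 and 1.14 within slide 3. The list call was lost within slide 2, in the deposited value table (0.76) and without E16 replicate 4 (1.03), the list median was 0.33 with quantile normalization, and the call of miR-125b-5p under quantile normalization (0.33) and in the deposited value table (0.76).

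**Figure D1:**
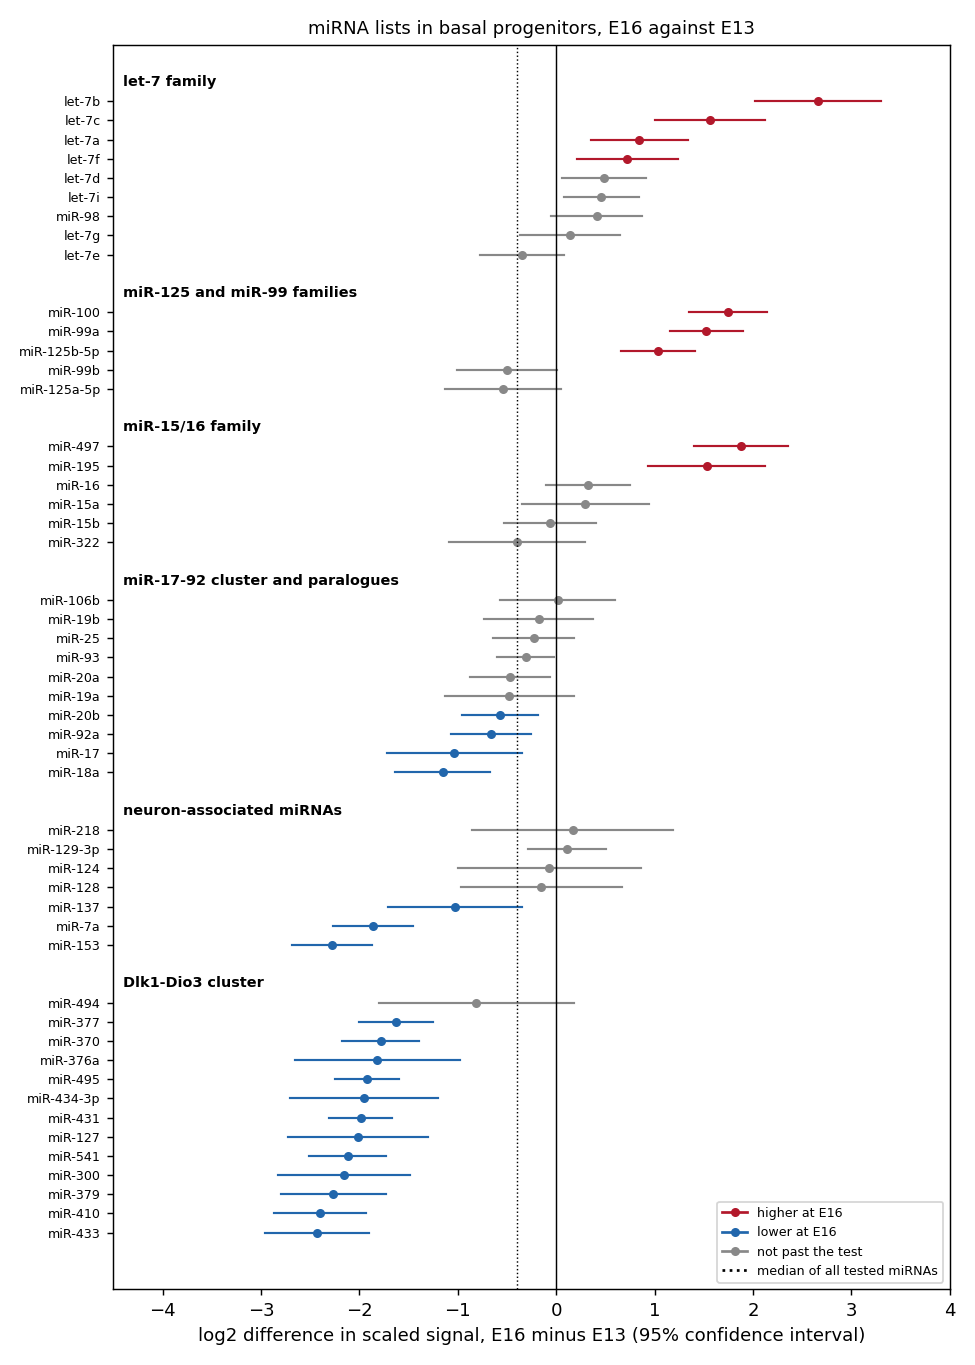
Log2 difference in scaled signal between E16 and E13 (x axis) for every tested member of 6 miRNA lists (y axis), with points for the limma estimates from 4 arrays per stage, bars for their 95% confidence intervals and a dotted line at the median of all tested miRNAs (-0.40). Points and bars that involve values at the floor are not exact. For miR-153, miR-431, miR-433, miR-541 and miR-370 every E16 value is at the floor, and the text gives bounds instead. let-7b (2.66) has the largest rise and 12 of the 13 Dlk1-Dio3 members are lower at E16, whereas the medians of the miR-17-92 list (-0.47) and the neuron-associated list (-0.15) turn to 0.35 and 0.67 with the percentile over all mouse probes.

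The miR-17-92 cluster and its paralogues, miRNAs tied to the proliferation of progenitors, had 10 tested members. Of these 4 fell, 0 rose and 6 did not pass the test, with the same counts adjusted over the list alone. Only 1 member was lower with the slide as a fixed block, within slide 2, with normexp correction and with the total signal per miRNA. With the mean of all probes 6 members were lower. miR-18a was 2.23-fold higher at E13 (log2 difference -1.15, SE 0.21, limma adjusted p = 0.0024), and its probe match lay on chromosome 14 from 115443094 to 115443111 (mm9). miR-17, detected on 3 arrays of each stage, had a log2 difference of -1.03 (SE 0.30), miR-92a of -0.66 (SE 0.18) and miR-20b of -0.57 (SE 0.17). With the percentile over all mouse probes none of these 4 passed, 2 other members were higher, miR-18a and miR-17 were at -0.33 and -0.21, and miR-92a and miR-20b turned to 0.16 and 0.25. The list median of -0.47 lay -0.07 from that of all tested miRNAs (camera adjusted p = 0.26), with -0.54 for the slide as a block, -0.26 within slide 2 and -0.89 within slide 3. Leaving out 1 array ended the call of miR-92a for E13 replicates 1 and 2 and E16 replicate 3 (-0.57 to -0.63), of miR-20b for E13 replicates 1, 3 and 4 and E16 replicates 2 and 4 (-0.40 to -0.57), and of miR-17 for E13 replicates 1, 3 and 4 and E16 replicates 1 and 4 (-0.77 to -1.05).

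Outside this list, miR-130b and miR-301b, neighbours on chromosome 16 (mm9 17124209 to 17124225 and 17124551 to 17124569), both fell. miR-130b was 2.16-fold higher at E13 (log2 difference -1.11, SE 0.14) and miR-301b 2.33-fold (-1.22, SE 0.23). Both overlap the gene 2610318N02Rik in the RefSeq annotation of GRCm38. The other falls among miRNAs detected on every array were those of miR-669f (-0.97), miR-342-3p (-0.83), miR-324-5p (-0.72), miR-103 (-0.59) and miR-107 (-0.42). With the percentile over all mouse probes none of these falls passed the test (miR-130b -0.29, miR-301b -0.40, miR-669f -0.15, miR-342-3p -0.01), and miR-324-5p, miR-103 and miR-107 turned to 0.10, 0.23 and 0.41. Leaving out 1 array ended the call of miR-669f for E13 replicates 1 and 4 (-0.94 and -0.90), of miR-324-5p for E13 replicates 1, 3 and 4 and E16 replicates 2 and 3 (-0.66 to -0.76) and of miR-107 for every array but E16 replicate 1 (-0.28 to -0.43). The probe of miR-669f holds repeats of TG, and its E16 values ran from -4.16 on replicate 1 to -3.07 on replicate 4. Other probes with such repeats also differed between these 2 arrays, and whether the repeats matter was not tested. Among the rises, miR-23a, whose gene neighbours Mir27a, had a log2 difference of 0.99 (SE 0.24) and miR-181a of 0.85 (SE 0.15). Under normexp correction both were smaller and did not pass (0.48 and 0.54), and within slide 3 miR-23a did not (0.44).

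The Dlk1-Dio3 cluster, an imprinted region of chromosome 12 with 58 miRNAs on the array, had 28 members above background on at least 1 E13 array and 10 on at least 1 E16 array. Of 13 tested members 12 fell and 1, miR-494, did not pass the test (log2 difference -0.81, SE 0.44), with the same counts adjusted over the list alone. Without E13 replicate 1, 2, 3 or 4 fewer members met the filter, and 8 of 9, 6 of 7, 6 of 6 and 6 of 6 were lower, as were 10 of 10 without E16 replicate 1. miR-494 was at 0.01 with the percentile over all mouse probes. No member was well above background on all 8 arrays, so that the list had no value under that filter. Of the 13 tested members the deposited value table held miR-434-3p alone, at -0.50 there against -1.95 in the main fit. Unscaled processed signals of the tested members lay between 7.26 and 63.9 on the E13 arrays. miR-410 was well above background on 4 E13 and 2 E16 arrays and 5.28-fold higher at E13 (log2 difference -2.40, SE 0.21, limma adjusted p = 3.3e-05, with E16 replicate 4 at the floor), and its probe match lay on chromosome 12 from 110981977 to 110981994 (mm9). miR-495, well above background on 3 E13 arrays and 1 E16 array, passed the test as lower at E16, but with 3 of its 4 E16 values at the floor the size of its fall is not given. miR-433, miR-541, miR-431 and miR-370 were well above background on all 4 E13 arrays and on no E16 array, and were at least 2.98-fold, 2.40-fold, 2.20-fold and 1.91-fold lower at E16. The list median was -1.99, or -1.82 with these 4 miRNAs at their bound and -1.59 relative to all tested miRNAs (camera adjusted p = 4.2e-07, and adjusted p = 0.16 with an estimated correlation). It was -2.17 with the slide as a block, -1.93 within slide 2, -2.07 within slide 3 and -1.21 with the mean of all probes. With the percentile over all mouse probes the list median was -1.50 and 12 members were lower, with quantile normalization it was -1.15 and 11 were, and with normexp correction, which adds an offset of 50 to each signal, it was -0.58 and 0 members passed. Mir410 and Mir541 overlap the long non-coding RNA gene Mirg, Mir370 overlaps Rian, and Mir431 and Mir433 overlap Rtl1, in the RefSeq annotation of GRCm38.

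Among the neuron-associated miRNAs, 3 of 7 tested members fell and 4 did not pass the test, with the same counts adjusted over the list alone. Without any one E13 array, where miR-153 was not tested, 1 member was lower, with the percentile over all mouse probes 1 was higher and 2 were lower, 2 of 6 were lower without E16 replicate 2, and within slide 3 6 of 7 were. miR-153 was well above background on all 4 E13 arrays and no E16 array and was at least 2.68-fold lower at E16. miR-7a was 3.63-fold higher at E13 (log2 difference -1.86, SE 0.18). Under normexp correction neither passed (-0.57 and -0.78). miR-137 had a log2 difference of -1.02 (SE 0.30), a call that was lost with the percentile over all mouse probes (-0.37), quantile normalization (-0.32) and normexp correction (-0.32), was kept with median centring (-0.97), and was lost without any one E13 array or E16 replicate 2 (-0.94 to -1.11), and the difference was -0.66 without E16 replicate 4. miR-124, which is abundant in neurons, had a log2 difference of -0.07 (SE 0.41), and miR-128 of -0.15 (SE 0.36), and both turned positive with the percentile over all mouse probes (0.75 and 0.67), with quantile normalization (0.02 and 0.03), with normexp correction (0.07 and 0.00088) and without E16 replicate 4 (0.36 and 0.27). Their E16 arrays spread with SDs of 0.90 and 0.78 against 0.30 and 0.26 at E13 (n = 4 each). Within slide 3 they were at -1.29 and -1.40, and within slide 2 at 0.05 and 0.16. For the whole list the median was -0.15, or 0.25 above that of all tested miRNAs (camera adjusted p = 0.45, and adjusted p = 0.65 with an estimated correlation). It was -0.48 with the slide as a block, 0.02 within slide 2 and -1.41 within slide 3.

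Both arms of the miR-9 hairpin, characteristic of neural progenitors and neurons, were well above background on every array. miR-9 had a log2 difference of -0.09 (95% confidence interval -0.54 to 0.36) and miR-9* of 0.33 (-0.31 to 0.96), and neither passed the test. With the percentile over all mouse probes both passed, at 0.73 and 1.15, within slide 3 both were lower, at -0.63 and -0.50, and within slide 2 miR-9 was at 0.21.

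The miR-15/16 family, regulators of the cell cycle, had 6 tested members, of which 2 rose and 4 did not pass the test, with the same counts adjusted over the list alone, and 5 were higher with the percentile over all mouse probes (list median 1.13). miR-497 and miR-195, neighbours on chromosome 11, were each well above background on 1 E13 and 3 E16 arrays. With 3 of the 4 E13 values of each at the floor, their log2 differences of 1.88 and 1.53 are not exact. Both calls were lost under normexp correction (0.20 and 0.14) and with the total signal per miRNA (2.49 and 2.21), and miR-195 did not pass within slide 3 (0.65). miR-16 had a log2 difference of 0.32 (SE 0.19) and miR-322 of -0.40 (SE 0.30), which was 0.42 with the percentile over all mouse probes. The list median was 0.31, or 0.71 above that of all tested miRNAs (camera adjusted p = 0.0079, and adjusted p = 0.36 with an estimated correlation), whereas the median per array differed by -0.05 between stages. The list call was lost without E13 replicate 3 (0.18) or E16 replicate 1 (-0.04), 2 (0.11) or 3 (0.11), where miR-497 and miR-195 were not tested. It was also lost with quantile normalization (0.17), normexp correction (0.17) and the filter on all 8 arrays (0.30), and the median turned to -0.08 in the deposited value table. The value for the list was 0.14 with the slide as a block, 0.46 within slide 2 and -0.35 within slide 3.

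**Figure D2:**
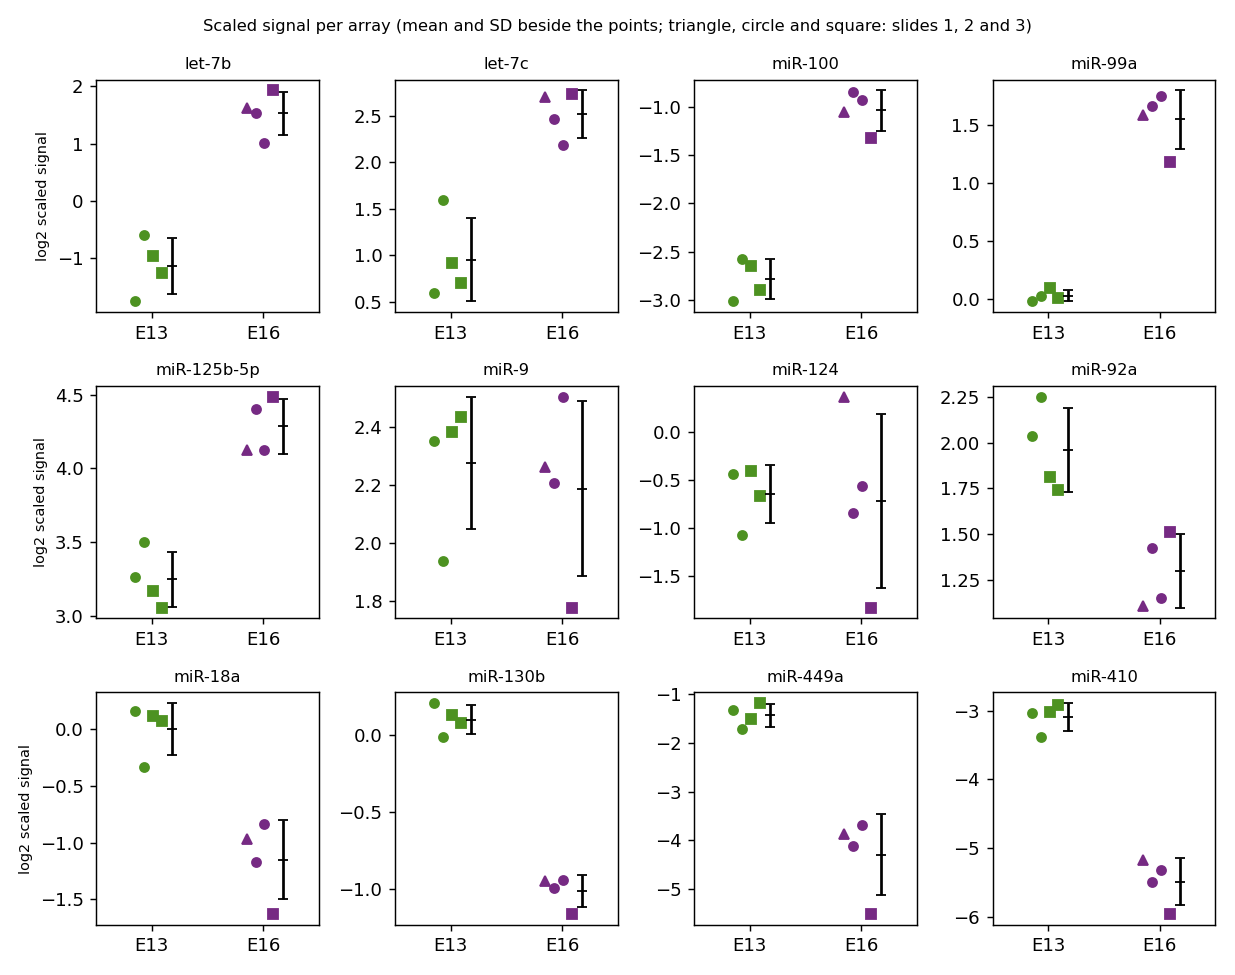
Log2 scaled signal (y axis) on each of the 4 E13 and 4 E16 arrays (x axis) for 12 miRNAs, with a dash and bar for the mean and SD and the marker shape for the slide. The values of both stages are separate for let-7b, let-7c, miR-100, miR-99a, miR-125b-5p, miR-92a, miR-18a, miR-130b, miR-449a and miR-410 and overlap for miR-9 and miR-124, and with the percentile over all mouse probes miR-92a, miR-9 and miR-124 turn positive (0.16, 0.73 and 0.75).

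The miR-30 family had 5 tested members and none passed the test, with log2 differences from 0.02 for miR-30d to 0.39 for miR-30e, whereas all 5 were higher with the percentile over all mouse probes (list median 1.09). Its list median was 0.27, or 0.67 above that of all tested miRNAs (camera adjusted p = 0.052, and adjusted p = 0.40 with an estimated correlation), with 0.24 for the slide as a block, 0.69 within slide 2 and -0.38 within slide 3. Of the 4 members of the miR-181 family, miR-181a rose and 3 did not pass the test, with log2 differences of 0.52 for miR-181c, 0.08 for miR-181b and -0.11 for miR-181d, whereas with the percentile over all mouse probes all 4 were higher (list median 1.12, miR-181d 0.71). The miR-181 list median was 0.30, or 0.70 above that of all tested miRNAs (camera adjusted p = 0.042, and adjusted p = 0.17 with an estimated correlation). Its call was lost without E13 replicate 3 (0.32) or 4 (0.31) or E16 replicate 4 (0.37) and within slide 2 (0.37). It was also lost with normexp correction (0.0954), the filter on all 8 arrays (0.30) and the deposited value table (0.47). The median was 0.32 with the slide as a block and 0.47 within slide 3. Adjusted over each list alone, the counts of both families were the same. In the miR-29 family, miR-29a alone was tested and had a log2 difference of 0.36 (SE 0.36), which was -0.07 with normexp correction.

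Lists of miRNAs of other cell types were then examined. No member of the lists for erythroid cells, leukocytes and microglia, endothelium, mesenchyme and muscle, hindbrain and spinal cord, embryonic stem cells or epithelia was well above background on any array, miR-451 and miR-126-3p included. Of 3 oligodendrocyte-lineage miRNAs, miR-219 (log2 difference -0.44, SE 0.29) and miR-338-3p (0.36, SE 0.38) were tested and did not pass, and miR-219 was at 0.38 with the percentile over all mouse probes. Of 8 miRNAs listed for choroid plexus and pigmented epithelium, only miR-449a was above background, on 4 E13 and 3 E16 arrays. Its probe match lay on chromosome 13 from 113827760 to 113827778 (mm9), and Mir449a overlaps Cdc20b in the RefSeq annotation of GRCm38. Its fall did not pass the test under normexp correction (-1.25).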

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

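The tests of dim arrays and of neurons for the Dlk1-Dio3 cluster, and those of dim signal, of neurons and of the slide of replicate 1 for E16 replicates 1 and 4, were chosen only after the result was seen.

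If all 8 arrays were exchangeable, which shared slides and litters do not assure, chance would rarely give the counts of miRNAs that differ. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many calls (50, with 0 as the highest of the other splits), and the same held for the 11 miRNAs higher (1 of 35, highest other 0) and the 39 lower at E16 (1 of 35, highest other 0). These counts rest on the same calls and are not separate tests. Only 18 splits keep the number of arrays of each stage on each slide (real count 50, highest other 0). That is too few for a share under 0.05, so that with slides kept chance cannot be excluded. Litters, which are not given per replicate, could not be kept. For the number of lists shifted by camera chance cannot be excluded: the real split gave 5, 4 of the 35 splits gave as many, and the highest other gave 6 (E13 replicate 1 with E16 replicates 1, 2 and 4 against the rest).

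The Dlk1-Dio3 cluster fell at E16 in 12 of 13 tested members. The dimmest E16 array, replicate 4, does not alone account for the fall. Without it the E16 arrays were on average brighter than the E13 arrays (75th percentiles of 546 and 316), and 12 of 13 members were still lower, with a median of -1.83. E16 replicate 3 (282) stayed dimmer than E13 replicates 2, 3 and 4 (317, 490 and 294). Array brightness as part of the cause cannot be excluded this way. Scaled probes of mghv-miR-M1-2, a viral miRNA, also lay at the floor on the bright E16 replicates 1 and 2. On the dim E16 replicate 4 its detected probes were at -3.48 and -3.44. Counts of members below every E13 array on the 2 brightest arrays, both of E16, had been looked at first and did not decide, with 6 of 13 members (2 of 140 other miRNAs) unscaled, and 12 of 13 (50 of 140) scaled, which the calls without overlap already imply. Whether more neurons in the E13 gate account for part of the fall could not be decided. The mean of miR-124 and miR-128 differed by -0.11 between stages (two-sided exact permutation test, p = 0.74), with an E16 SD of 0.83. The cluster median per array differed by -2.25. The mean of the 2 miRNAs minus the cluster median rose by 2.14 (exact permutation p = 0.029). That p mostly restates the fall for which the cluster was examined. miR-124 and miR-128 themselves thus gave no sign of falling with the cluster. However, miR-124*, the other arm of the miR-124 hairpin, was lower at E16 (log2 difference -0.86, SE 0.19, limma adjusted p = 0.0058). It is named here after its value was seen. The falls of miR-124* and of miR-153, miR-7a and miR-137 of the neuron-associated list keep the explanation open, and the sorting gate is not given in the sources used here. A difference between the stages in the progenitors themselves, which the design names, stays open and was not tested.

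E16 replicates 1 and 4 departed in opposite directions from the other E16 arrays along the second principal component. The departures of slide 3 from slide 2 correlated at r = -0.37 between E13 and E16 arrays across miRNAs, and so showed no shift shared by both stages on slide 3. They rest on few E13 arrays and on replicate 4 as the only E16 array there, so that a slide effect on replicate 4 cannot be excluded. Replicate 1 cannot be told apart from its slide, which held 0 other arrays. Dim signal, with r = 0.10 between the departure of the dimmest E13 array and replicate 4 minus replicate 1, cannot be told apart from other causes, because that E13 array was brighter than E16 replicate 4. A different share of neurons cannot be told apart from other causes. The neuron-associated list differed by -1.31 between replicates 4 and 1, against -0.54 for all tested miRNAs. That was percentile 5.61 of 10000 random lists of the same size and brightness, short of the limit set for the test. The miRNAs furthest higher on replicate 4, such as miR-690 (3.82), miR-467f (3.65), miR-1187 (3.45) and miR-709 (3.35), are not on the neuron-associated list. On that side, the probes of miR-467f, miR-1187, miR-574-5p, miR-466i, miR-466f-3p and miR-466g hold repeats of TG or CA. Whether these repeats matter was not tested. Apart from the share of neurons no biological explanation was tested, since the labels name no difference between these replicates.

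Single arrays stood apart from the others of their stage in 5 of 99 groups of 4 values. Chance gives about 1 in 20 such groups, but in 3 of the 5 the other values are tied at the floor, so that the count cannot be set against that rate. miR-497 at E13 was -5.81 on replicate 3 and at the floor of -5.96 on the other arrays. miR-195 at E13 was -5.62 on replicate 3 and at the floor on the others, and at E16 it was -5.14 on replicate 4, with the nearest array at -4.13. miR-9 at E13 was 1.94 on replicate 2, with the nearest array at 2.35. miR-495 at E16 was -5.87 on replicate 1 and at the floor on the others. Of 39 viral miRNAs on the array, 1, mghv-miR-M1-2 of a mouse herpesvirus, had a probe well above background, on 7 arrays. The plan read viral probes as background. On E13 replicate 1 its detected probes were at -3.86 to -3.70, near miR-431 and miR-370 there (-3.75 each). On E13 replicates 3 and 4 they were at -5.28 to -4.34, below miR-431 (-4.00 and -4.01). Being well above background at such levels therefore need not mean a specific signal. All probes of mghv-miR-M1-2 were at the floor on the bright E16 replicates 1 and 2. On E16 replicate 4, the dimmest array, its detected probes were at -3.48 and -3.44, while miR-431 and miR-370 were at the floor there. Scaled values near background may thus depend on array brightness, which was not tested.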

How the results depend on the processing

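Centring on the median and list counts without E16 replicate 4 were chosen only after the result was seen. Of the values of single named miRNAs under the alternatives, 923 kept their direction and their side of the threshold, 137 kept their direction and lost the call, 27 gained one and 43 turned. let-7b, miR-100 and miR-99a kept their calls under every alternative that gave a value, with ranges of 2.17 to 3.48, 0.99 to 2.57 and 1.14 to 2.35. Signal over background limits what the dim arrays can show: the lowest signal of a probe well above background was -3.53 (log2) on E16 replicate 4 and -6.19 on E16 replicate 2. Where no construction is named below, the cause was not tested.

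The percentile over all mouse probes is set largely by probes near background, since 131 to 344 of the 1759 were well above it on an array. It shifts differences between values above the floor alike and those that involve the floor by less. With it 46 miRNAs were higher and 16 lower (25.8% of calls lower, against 78%). The medians of the miR-17-92 and neuron-associated lists turned to 0.35 and 0.67 and that of miR-30 passed at 1.09. miR-103 (0.23), miR-107 (0.41), miR-124 (0.75), miR-128 (0.67), miR-181d (0.71), miR-20b (0.25), miR-219 (0.38), miR-322 (0.42), miR-324-5p (0.10), miR-9 (0.73), miR-92a (0.16) and miR-99b (0.32) turned. With quantile normalization 22 miRNAs were lower (62.9% of calls), the lists for miR-15/16 (0.17) lost and miR-17-92 (-0.39) and miR-30 (0.33) gained a call, the neuron-associated list turned to 0.0243, and miR-124 (0.0243), miR-128 (0.0325), miR-181d (0.0252) and miR-9* (-0.0567) turned. With normexp correction, whose offset shrinks low signals by construction, 7 miRNAs differed, 5 higher and 2 lower (10 and 8 at an unadjusted p under 0.05; 28.6% of calls lower). The miR-15/16 (0.17) and miR-181 (0.0954) lists lost and miR-17-92 (-0.32) gained a call, and miR-124 (0.0664), miR-128 (0.00088), miR-129-3p (-0.0831) and miR-29a (-0.0682) turned. With median centring 74% of calls were lower and the miR-30 list passed (0.32).

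With the total signal per miRNA, 31 of 179 miRNAs differed, 7 higher and 24 lower, the miR-30 list passed (0.42), and miR-124 (0.0601) and miR-181d (0.0485) turned. With the deposited value table, which holds fewer miRNAs, 24 differed and 11 were lower (45.8% of calls), the miR-125 and miR-99 (0.76) and miR-181 (0.47) lists lost a call, miR-17-92 (-0.42) gained one and miR-15/16 turned to -0.0821. With the filter on all 8 arrays, 19 of 75 miRNAs differed and 10 were lower, the miR-15/16 (0.30) and miR-181 (0.30) lists lost and miR-17-92 (-0.47) gained a call. Without a filter the miR-17-92 (-0.47) and miR-30 (0.27) lists gained a call, and the Dlk1-Dio3 median was 0 where members at the floor at both stages differ by 0. The lower floor (0.27) and the slide as a fixed block (0.24) brought the miR-30 list past the threshold.

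With an estimated correlation the lists for Dlk1-Dio3 (median -1.99, adjusted p = 0.16), let-7 (0.49, 0.20), miR-125 and miR-99 (1.04, 0.17), miR-15/16 (0.31, 0.36) and miR-181 (0.30, 0.17) no longer passed, and no list that gained a call under another setting passed with an estimated correlation under that setting (adjusted p = 0.25 to 0.51). With fry, which asks whether members move one way on balance, miR-15/16 (0.31) did not pass and miR-17-92 (-0.47) and the neuron-associated list (-0.15) did.

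Within slide 2, which holds fewer samples, 25 miRNAs were lower, the miR-125 and miR-99 (0.89) and miR-181 (0.37) lists lost and miR-30 (0.69) gained a call, the neuron-associated list turned to 0.0187, and miR-124 (0.0537), miR-128 (0.16), miR-181b (-0.0692), miR-322 (0.0172) and miR-9 (0.21) turned. Within slide 3, whose only E16 array is replicate 4, so that the values describe that array, 100 miRNAs differed and 87 were lower. The miR-15/16 and miR-30 lists turned to -0.35 and -0.38, as did miR-16 (-0.12), miR-181c (-0.14), miR-181d (0.34), miR-29a (-0.93), miR-30a (-0.38), miR-30b (-0.42), miR-30e (-0.42), miR-338-3p (-0.93), miR-9* (-0.50) and miR-99b (0.0668).

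The replicate numbers did not pair the samples: deviations from the stage means correlated at -0.09, 0.06, 0.28 and -0.14 between arrays of the same number, and not every array correlated best with its own number. With the replicate number as a block, 43 miRNAs differed, 10 higher and 33 lower, and the miR-30 list passed (0.27).

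Leaving out each array in turn gave 8 to 22 miRNAs higher, 21 to 43 lower and 30 to 65 in all. The number of miRNAs detected per array differed by -32.5 (without E16 replicate 2) to -1.17, and by -22.5 with the scanner software's own detection call. List medians ranged from 0.98 to 1.12 for miR-125 and miR-99, -0.0416 to 0.56 for miR-15/16, -0.79 to 0.15 for the neuron-associated list, 0.14 to 0.38 for miR-30 and 0.27 to 0.37 for miR-181. Differences ranged from -0.20 to 0.11 for miR-9, -0.00581 to 0.19 for miR-181b, -0.42 to 0.36 for miR-124 and -0.41 to 0.27 for miR-128. Without E16 replicate 4, 6 let-7 members, 3 of miR-125 and miR-99, 4 of miR-15/16, 1 of miR-30 and 2 of miR-181 were higher, and 2 of miR-17-92, 3 neuron-associated and 12 Dlk1-Dio3 members were lower. Over all the arrays left out in turn, 2 to 6 let-7, 0 to 4 miR-15/16, 0 to 1 miR-30 and 1 to 2 miR-181 members were higher, and 1 to 3 of miR-17-92, 1 to 3 neuron-associated and 6 to 12 Dlk1-Dio3 members were lower, the last because fewer members met the filter without an E13 array. The remaining alternatives (the mean of all probes, the slide as a random block, eBayes with trend and robust options) changed no list call and moved no count of all calls by over 1.5 times, but with the mean of all probes the Dlk1-Dio3 median was -1.21, 2 miR-181 members were higher and 6 of miR-17-92 were lower.

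Single calls were also lost where the direction held. The percentile over all mouse probes ended those of miR-301b, miR-18a, miR-130b, miR-669f, miR-342-3p, miR-17 and miR-137, and quantile normalization those of miR-125b-5p, let-7f, miR-669f, miR-324-5p, miR-107, miR-17 and miR-137. Of the named calls, normexp correction left those of let-7b, miR-100, let-7c, miR-99a, miR-125b-5p, miR-18a and miR-130b. The slide as a fixed block ended those of let-7a, let-7f, miR-92a, miR-20b, miR-107 and miR-17, slide 3 those of miR-23a, let-7f, miR-92a and miR-195, and slide 2 those of let-7c, let-7a, let-7f, miR-301b, miR-18a, miR-669f, miR-324-5p, miR-103, miR-20b, miR-107, miR-17 and miR-137. The total signal ended those of miR-23a, let-7f, miR-669f, miR-342-3p, miR-324-5p, miR-92a, miR-103, miR-20b, miR-107, miR-17, miR-497, miR-195, miR-7a and miR-137. The replicate block ended those of let-7f, miR-92a, miR-20b, miR-107 and miR-137, median centring those of miR-92a and miR-107, the lower floor those of miR-107 and miR-137, the deposited value table those of miR-125b-5p, let-7f and miR-107, and the random slide block that of miR-107. No filter, with more miRNAs to adjust for, ended those of miR-23a, let-7a, let-7f, miR-669f, miR-324-5p, miR-92a, miR-20b, miR-17 and miR-137.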

Other observations

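The test of genomic clusters, the comparison of the chromosome 17 miRNAs and the permutation tests of list medians per array were chosen only after the result was seen.

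miR-99b, let-7e and miR-125a-5p, which lie together on chromosome 17 (mm9 17967165 to 17967804), had log2 differences that averaged -0.46, against 1.06 for the other 11 members of the let-7, miR-125 and miR-99 lists, all 11 of which were above 0. On each array the mean of the 3 minus the mean of the 11 does not depend on the array's scaling factor. It differed by -1.52 between stages, and all 4 E16 arrays lay below every E13 array. The 3 were grouped after they were seen to be the only members below 0, so this is an observation and not a test. Under the percentile over all mouse probes miR-99b, let-7e and miR-125a-5p were at 0.32, 0.47 and 0.28, and which side changed stays open.

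Neighbouring miRNAs, arms of 1 hairpin included, moved alike. Over 50 tested miRNAs in 19 clusters, with neighbours within 50000 bp on mm9 and the Dlk1-Dio3 cluster left out, log2 differences within a cluster were 0.379 apart on average, against a median of 0.774 when the same values were shuffled (one-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). Shared transcription of neighbouring miRNAs could give this. However, most clusters hold both arms of 1 hairpin, as those of miR-30a, miR-324, miR-342 and miR-574 do, and some hold probes alike in sequence. The test does not tell arms of 1 hairpin from neighbouring miRNA genes.

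List medians were also compared per array, relative to the array's median over all tested miRNAs, with exact permutation tests adjusted over 8 lists. They differed by 0.94 for let-7, 0.83 for miR-125 and miR-99, 0.76 for miR-30, 0.66 for miR-181 and -1.80 for Dlk1-Dio3 (two-sided exact permutation p = 0.029 and adjusted p = 0.046 each), and by 0.39 for miR-15/16, 0.06 for miR-17-92 and -0.03 for the neuron-associated list (adjusted p = 0.19, 0.36 and 0.94, exact permutation). Without the array median taken off the design let no list pass unless at least 5 of the 8 reached the smallest p, and 3 did: let-7 (0.49), miR-17-92 (-0.38) and Dlk1-Dio3 (-2.25) had an adjusted p of 0.076 each, the neuron-associated list (-0.47) of 0.17, miR-125 and miR-99 (0.39) of 0.18, miR-30 (0.31) and miR-181 (0.21) of 0.26 and miR-15/16 (-0.05) of 0.91 (exact permutation). The value 0.029 is the smallest p that 4 against 4 arrays can give.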
